A study of Mus musculus with 8 samples.

How the data were processed

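Total RNA of mouse embryonic stem cells was extracted with Trizol, labelled with biotin and hybridised to Affymetrix arrays, per the labels. The deposited values are intensity signals, 1 per probe set and array, on a linear scale. Per the submitters' processing notes they were made with MAS5, whose version is not given in the sources used here. The table held 45101 probe sets on 8 arrays with 0 missing values, and the lowest value was 1. The labels' treatment protocol mentions virus or siRNA, while the design text and sample labels name shRNA and lipofection for J1.

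The 8 arrays fell into 4 groups of 2 by the transfection label and the cell line: J1 control, J1 Rif1 shRNA, F1 control and F1 Rif1 shRNA. The groups, the tests, the gene lists, the naming rule and the alternatives were chosen before the data were examined, except where said otherwise. The 2% trimmed mean of the deposited signal was 193 to 197 on J1 arrays and 301 to 309 on F1 arrays. Since these differed by over 5%, the values were quantile normalized across all arrays as log2(signal + 18), where 18 is the 10th percentile of all values. The 64 control probe sets were left out. Probe sets above the 40th percentile of their array on at least 2 arrays were kept, which left 31605. Correlations between the replicates of a group were 0.991 to 0.997, and no pair held identical values throughout.

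Group means were fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with an intensity trend). There were 4 residual degrees of freedom and 6.94 prior degrees of freedom. A probe set passed at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The contrasts were Rif1 shRNA minus control in J1, the same in F1, and the F1 effect minus the J1 effect.

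Gene names came from the platform annotation. Of 45037 probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none here; 34754 of those with 1 symbol matched a RefSeq gene table and 0 symbols changed. Probe sets with several symbols named no gene. A total of 26335 tested probe sets had 1 symbol, for 14714 genes. For the lists, each gene was taken at its brightest kept probe set.

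The 20 gene lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 20 lists, and again with an estimated correlation. The estimated version uses only the residual degrees of freedom of the fit, so it can lose calls at a low correlation too. They covered the 2-cell stage, pluripotency, primed epiblast, primitive endoderm, streak and mesoderm, neural ectoderm, trophoblast, telomere maintenance, break repair, p53 targets, heterochromatin, germline, DNA replication, mitosis, feeder fibroblasts, interferon, imprinting, glycolysis and hypoxia, cholesterol synthesis, and the unfolded protein and amino acid stress response. The text names every Rif1 probe set. For each knockdown it names the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold whose arrays did not overlap between groups. For the difference it names 6 each way, for the overlap up to 6 each way, and from each list the 4 members with the smallest p. Of these list members, Mga, Rrm2 and Ctc1 are counted among the named genes but not described in the results. List members outside this rule that spell out a count of 5 or fewer, and Pou5f1, Nanog, Col1a1, Col3a1, Fn1, Col1a2, Postn, Arg2, Ndrg1, Usp9y and Xist, were chosen after their values were seen.

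The fit was tested on 20 simulated data sets with 200 changed probe sets per comparison. With one spread for both settings and changes placed on the normalized scale, 7.13% of J1 calls and 7.59% of F1 calls were false. With each setting's own spread these shares were 23.2% and 0.493%; 51.4% of 1.41-fold, 98.8% of 2-fold and 99.8% of 4-fold changes were recovered in J1, and 46.8%, 99.2% and 99.8% in F1. With changes placed on the deposited scale and each setting's own spread, 28.2% of J1 calls were false, and a log2 change of 1 was estimated as 1.10 in J1 and 0.913 in F1, so quantile normalization stretched J1 changes and shrank F1 changes there, although single genes such as Rif1 moved the other way. With own spreads and only the 4 arrays of a setting, 8.40% of J1 and 8.23% of F1 calls were false on the normalized scale.

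Alternatives were other offsets, filters, scalings, spreads, thresholds, blocks, list tests and each array left out in turn. After the values were seen, the deposited scale, normalization within each setting, a crossed replicate block and a count without 3 lists and Y-linked genes were added. Coordinates were not used here except the order of genes along chromosomes.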

Results

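Gene expression was measured on 8 Affymetrix mouse arrays in embryonic stem cells carrying a control short hairpin RNA (shRNA) or one against Rif1, a gene whose protein acts at telomeres, DNA breaks and replication origins. The cells were grown on feeder cells. In the first setting, J1 cells (strain 129S4/SvJae) were transfected and collected after 48 h. In the second setting, F1 cells (C57BL/6xC3H) with a stable knockdown were collected at passage 16. Each setting had 2 control arrays and 2 Rif1 shRNA arrays. The labels of the F1 control arrays carry the shRNA control under transfection but also the name of the stable knockdown line under cell line. The 2 arrays of a group are not stated to come from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Array medians of the deposited signal lay between 61.1 and 69.4. The number of arrays limits the precision of every value. Fold changes are on the log2(signal + 18) scale after normalization. The offset of 18 shrinks the change of dim genes.

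The first question was how far Rif1 itself was lowered. In J1 cells, the brightest Rif1 probe set had a deposited signal of 2918 ± 430 (SD, n = 2) in control arrays and 1278 ± 26.0 (SD, n = 2) in Rif1 shRNA arrays. Its log2 fold change was -1.08 (SE 0.08, limma adjusted p = 6.54e-05), which left 47.2% of the control level. In F1 cells the signal was 4239 ± 11.8 (SD, n = 2) in controls and 1373 ± 48.2 (SD, n = 2) in knockdown cells. The log2 fold change was -1.74 (SE 0.08, limma adjusted p = 3.23e-07), which left 29.9%. The other 3 Rif1 probe sets fell as well, by 1.35, 1.19 and 1.20 on the log2 scale in J1 and by 1.57, 2.02 and 1.63 in F1. The first of these did not pass in J1 without control replicate 1 (adjusted p = 0.118), control replicate 2 (0.186), Rif1 shRNA replicate 1 (0.0724) or Rif1 shRNA replicate 2 (0.0879). At the brightest probe set, Rif1 fell further in F1 than in J1 (difference -0.66, limma adjusted p = 0.00454). Of the other 3, in the order given, the differences were -0.22, -0.82 and -0.44 (limma adjusted p = 0.805, 0.00769 and 0.285), so 2 of the 4 passed. The probe set with -0.22 was near background in F1, at 81.9 ± 35.1 in controls and 15.0 ± 16.7 in knockdown arrays (SD, n = 2). Its difference depended on the offset, at -1.07 with no offset and 0.49 with an offset 4 times larger, so its F1 fall is poorly measured. With values as deposited the brightest probe set had -1.17 in J1 and -1.61 in F1, and the difference was -0.44 (adjusted p = 0.0343).

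**Figure D1:**
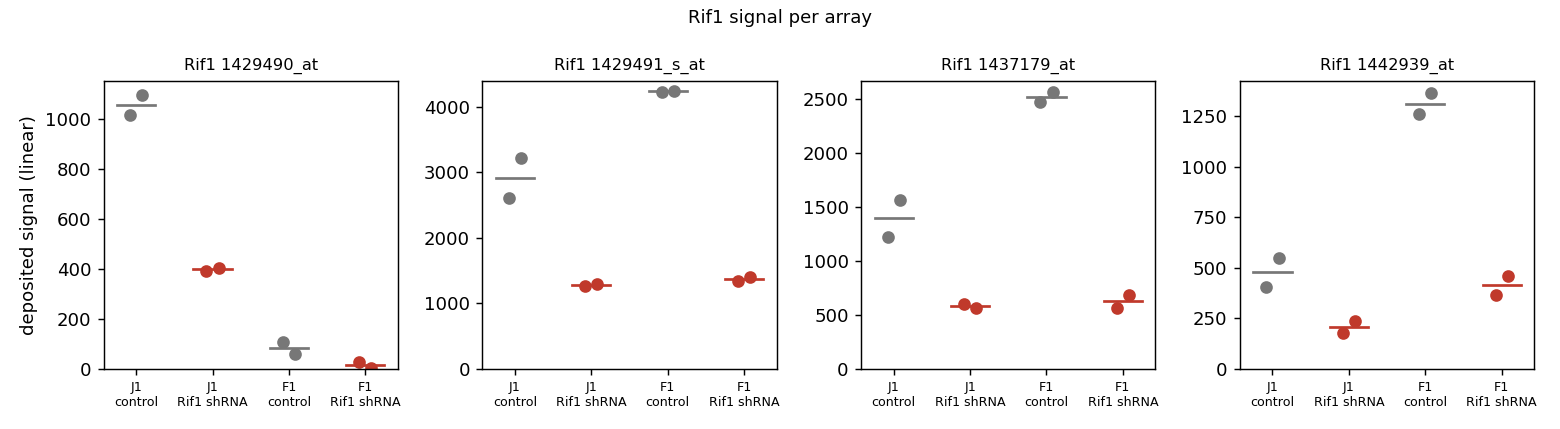
Deposited Rif1 signal (linear axis) per array for the 4 Rif1 probe sets, in grey for control and red for Rif1 shRNA, with the mean of the 2 arrays as a line. At the brightest probe set the J1 means were 2918 and 1278 and the F1 means 4239 and 1373.

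The next question was which genes had changed 48 h after transfection of J1 cells. The predicted gene Gm20767 and genes expressed in 2-cell embryos led the rises. Gm20767 rose 11.5-fold (log2 fold change 3.52, adjusted p = 2.40e-08), from a signal of 50.1 ± 11.6 to 560 ± 26.6 (SD, n = 2). AF067061, on the 2-cell list, rose 6.69-fold (adjusted p = 2.29e-08) and Usp17la, a deubiquitinase gene of the same list, 5.14-fold (adjusted p = 1.74e-07). Acta2, which encodes smooth muscle actin, fell most (log2 fold change -1.88, adjusted p = 3.61e-05), from 682 ± 80.9 to 187 ± 23.4 (SD, n = 2).

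Of 31605 probe sets tested in J1, 1004 passed the threshold, 455 higher and 549 lower in Rif1 shRNA arrays. More were lower than higher, but this balance was not stable: 146 were higher and 83 lower without control replicate 2, 590 and 394 without Rif1 shRNA replicate 2, and 179 and 171 with no intensity trend. Only 33 of the higher and 9 of the lower changed at least 2-fold. Further large rises were those of H1f2, a linker histone gene (log2 fold change 1.99), BC080696 (1.74), Tcstv3 (1.498), 3110040M04Rik (1.39), the germ cell gene Dazl (1.32), Abcf2 (1.28), Sp110 (1.22), Slc25a31 (1.20) and Ubtfl1 (1.13). Their adjusted p ran from 6.15e-07 for H1f2 to 0.00257 for Ubtfl1. Further large falls were those of Sfmbt1 (-1.05), Lpp (-1.05), the actin-binding gene Tagln (-1.01), Oip5os1 (-0.97), Rc3h2 (-0.95), Prss23 (-0.94), Pmepa1 (-0.91), the collagen gene Col5a2 (-0.90), Vgll3 (-0.90) and Prkca (-0.89). Their adjusted p ran from 0.000676 for Sfmbt1 to 0.00769 for Prss23. Prss23 and Col5a2 did not pass without control replicate 1 (adjusted p = 0.0644 and 0.0544), nor Oip5os1 without control replicate 2 (adjusted p = 0.0551). Each of these genes is given at 1 probe set. None of the other tested probe sets passed in J1 for Abcf2 (0 of 1), Col5a2 (0 of 1), Sp110, Prss23 and Prkca (0 of 2 each), and 1 of 6 did for Rc3h2 and for Lpp. Nor did any pass for Tert, Lamc1 and Idi1 (0 of 1 each), Krt8 and Pgk1 (0 of 2 each) and Ndn (0 of 5), named below.

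The J1 threshold was lenient. J1 arrays had a median residual SD of 0.115 and F1 arrays of 0.0658, while the fit gave both settings one spread. In simulations with each setting's own spread, 23.2% of the J1 calls were false, against 0.493% of the F1 calls. The false share depends on how many probe sets truly change, which was set at 200 per comparison. Noise was also drawn separately for each probe set, so these shares need not hold for the calls made here. With only the 4 J1 arrays in the fit, 280 probe sets passed (152 higher, 128 lower), 274 of them among the 1004. Of 53 named J1 probe sets past the threshold, 43 stayed past it in that fit. The ones that did not were those of Krt8, Fbxo15, Tert, Mki67, Anxa1, S100a6, Ndn, Ankrd37, Fdps and Idi1. The J1 count was 346 without control replicate 1, 229 without control replicate 2, 1763 without Rif1 shRNA replicate 1, and 621, 622, 489 and 495 without F1 control replicate 1 or 2 and F1 Rif1 shRNA replicate 1 or 2. Without J1 control replicate 1, 16 of the 53 named probe sets no longer passed (adjusted p from 0.0544 to 0.183), among them those of Aldoc, Pgk1, Ccng1, Mest and Nupr1, and without J1 control replicate 2 it was 18 (0.0530 to 0.188), among them that of Crabp1. Without Rif1 shRNA replicate 1 it was 3 (0.0724 to 0.119) and without replicate 2 it was 8 (0.0501 to 0.141). Without an F1 control array 4 no longer passed (0.0631 to 0.0920), those of Krt8, Fbxo15, Tert and S100a6, and without an F1 Rif1 shRNA array 5 (0.0630 to 0.104), those of Krt8, Fbxo15, Tert, Ndn and Nupr1. Control and knockdown arrays of J1 also differed in a sign of RNA quality: the 3'-to-5' signal ratio of actin was 2.71 and 2.61 in controls and 2.18 and 2.17 in Rif1 shRNA arrays, against 1.33 to 1.41 on F1 arrays.

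Among the 20 gene lists, 10 stood apart from other genes in J1 (camera with a preset correlation, limma), and 0 did with an estimated correlation. On the 2-cell list, 6 of 13 measured genes rose and 0 fell (8 and 0 adjusted over the list alone), with a median log2 fold change of 0.57 (adjusted p = 3.98e-10, and adjusted p = 0.213 with an estimated correlation). Besides AF067061, Usp17la, Sp110, Tcstv3 and Ubtfl1, these included Arg2 (0.79). Tcstv1 had 0.14 (adjusted p = 0.567). On the germline list, 7 of 28 rose and 0 fell (10 and 1 adjusted over the list alone; adjusted p = 1.57e-05, and adjusted p = 0.213 with an estimated correlation). Dazl and the mitochondrial carrier gene Slc25a31 rose most among them, and 4 rose without either control replicate 1 or control replicate 2.

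**Figure D2:**
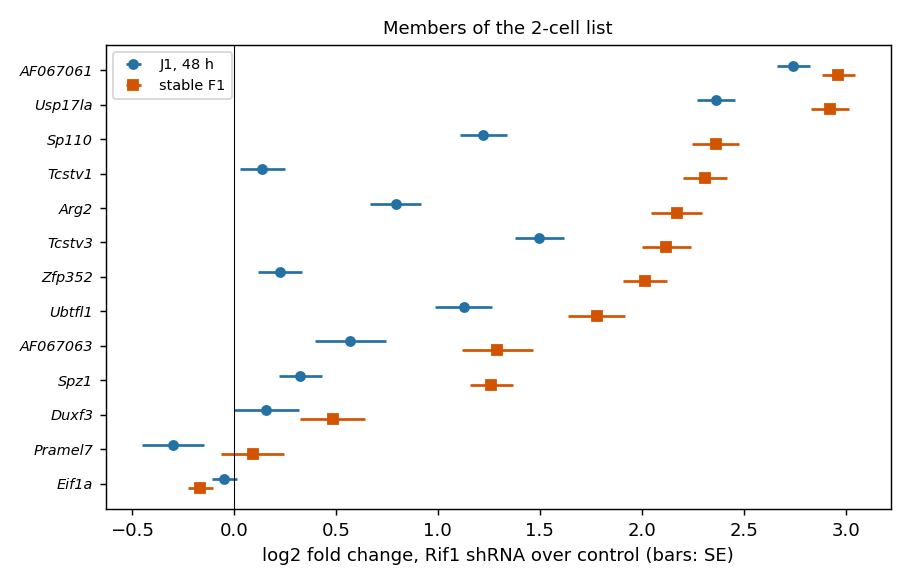
Log2 fold change of Rif1 shRNA over control (horizontal axis, bars SE) for the 13 measured members of the 2-cell list, as circles for J1 and squares for F1. AF067061 and Usp17la rose in both settings, while Tcstv1 had 0.14 in J1 and 2.31 in F1.

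Genes of glycolysis and the hypoxia response were higher in J1 Rif1 shRNA arrays as a list. Of 27 measured, 10 rose and 0 fell (20 and 0 adjusted over the list alone), with a median log2 fold change of 0.44 (adjusted p = 4.49e-14, and adjusted p = 0.244 with an estimated correlation). Members were Ankrd37 (0.64), the glycolytic enzyme genes Aldoc (0.65) and Pgk1 (0.35), and Ndrg1 (0.93). Single arrays moved this count: 0 members rose without either control replicate, 21 without Rif1 shRNA replicate 1 and 2 without Rif1 shRNA replicate 2. It was 6 without F1 control replicate 2 or either F1 Rif1 shRNA replicate. With only the 4 J1 arrays in the fit, 3 rose.

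Smaller shifts were seen on 3 further lists that fell and 2 that rose in J1. On the mitosis list, 3 of 27 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 1.76e-05, and adjusted p = 0.213 with an estimated correlation): Mki67, Cenpf and Aurkb. On the feeder fibroblast list, 7 of 26 fell and 0 rose (8 and 0 adjusted over the list alone; adjusted p = 0.000259, and adjusted p = 0.213 with an estimated correlation), led by Acta2 and Tagln, with 2 fallen without control replicate 1. The median of that list was -0.09, and the collagen genes Col1a1 and Col3a1 had 0.11 and 0.15 (adjusted p = 0.829 and 0.640). On the primitive endoderm list, 4 of 28 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 0.000370, and adjusted p = 0.215 with an estimated correlation). These were the basement membrane genes Col4a1, Col4a2, Lama1 and Lamc1. On the unfolded protein and amino acid stress list, 3 of 26 rose and 0 fell (8 and 2 adjusted over the list alone; adjusted p = 0.00330, and adjusted p = 0.213 with an estimated correlation): Ddit3, Nupr1 and Pdia6. On the imprinted list, Cdkn1c, Mest and Ndn rose and Peg3 fell among 24 (3 and 1 adjusted over the list alone; adjusted p = 0.00580, and adjusted p = 0.335 with an estimated correlation).

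The p53 list was lower in J1, with 5 of 24 fallen and 2 risen (11 and 5 adjusted over the list alone; adjusted p = 0.00508, and adjusted p = 0.345 with an estimated correlation). Zmat3, Polk, Trp53inp1, Perp and Ccng1 fell, and the apoptosis genes Pmaip1 and Bcl2l11 rose. On the heterochromatin list, 0 of 39 rose and 0 fell with limma (0 and 0 adjusted over the list alone), and the list test passed (median -0.05, adjusted p = 0.0367, and adjusted p = 0.364 with an estimated correlation). That call was lost without control replicate 2 (adjusted p = 0.267) and without Rif1 shRNA replicate 1 (adjusted p = 0.490), and also with the filter at the 60th percentile (0.0634) and a crossed block (0.0505). The imprinted call was also lost without Rif1 shRNA replicate 1 (adjusted p = 0.0789).

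The other 10 lists did not pass in J1. On the pluripotency list (adjusted p = 0.0517), Stat3 (-0.68), Tfcp2l1, Zscan10 and Sall4 fell and Tex19.1 and Fbxo15 rose among 34 (7 and 2 adjusted over the list alone). Pou5f1 had -0.02 and Nanog -0.08 (adjusted p = 0.943 and 0.437). The list passed without J1 control replicate 1 (adjusted p = 0.0337), F1 control replicate 1 or 2 (0.0446 and 0.0445), or F1 Rif1 shRNA replicate 1 or 2 (0.0434 and 0.0424). It also passed with values as deposited (adjusted p = 0.0109), with normalization within each setting (0.0441), with no filter on dim probe sets (0.0356) and with only the 4 J1 arrays (0.0380). On the trophoblast list (adjusted p = 0.532), Krt18 and Tfap2c fell and Ddah1 and Phlda2 rose among 17 (3 and 4 adjusted over the list alone). On the neural list (adjusted p = 0.368), Crabp1 and Crabp2 rose among 23 (3 risen and 2 fallen adjusted over the list alone). Tert, the telomerase gene, fell by 0.54 as the only member past the threshold among 28 on the telomere list (1 fallen adjusted over the list alone; list adjusted p = 0.689). The median of the telomere list was 0.01 and its test pointed down, and the median turned to -0.004 with values as deposited. On the DNA replication list (adjusted p = 0.667), Mcm4, Mcm5 and Topbp1 fell and Orc4 and Orc6 rose among 47 (8 and 3 adjusted over the list alone). On the break repair list (adjusted p = 0.223), Trp53bp1 fell and Mad2l2 rose among 35 (2 and 1 adjusted over the list alone). On the cholesterol list (adjusted p = 0.603), Hmgcs1 and Idi1 fell and Fdps rose among 20 (2 and 1 adjusted over the list alone). On the primed epiblast, streak and interferon lists 0 members passed among 19, 19 and 24 (list adjusted p = 0.689, 0.0601 and 0.678). The streak list passed, higher in knockdown arrays, with values as deposited (adjusted p = 0.0261), with the filter at the 60th percentile (0.0343), with a crossed block (0.0418) and with the mean of all probe sets of a gene (0.0488). Adjusted over the list alone, 1 rose and 1 fell among primed epiblast genes, 0 passed among streak genes and 1 fell among interferon genes. With limma, 5404 of all 31605 probe sets had an unadjusted p under 0.05.

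In stable F1 knockdown cells the changes were more numerous and larger. The first 3 genes named for J1 rose here as well: AF067061 7.79-fold (adjusted p = 9.93e-09), Usp17la 7.58-fold (adjusted p = 2.05e-08) and Gm20767 7.25-fold (adjusted p = 6.46e-08). The epithelial keratin genes Krt18 and Krt8 rose 8.83-fold and 8.75-fold, Krt18 from a signal of 480 ± 1.77 to 4330 ± 239 (SD, n = 2). Eif2s3y, a gene on the Y chromosome, rose 17.3-fold (log2 fold change 4.12, adjusted p = 3.85e-10), from 20.6 ± 1.03 to 936 ± 34.3 (SD, n = 2). The signal of the F1 controls was near background, while J1 control and knockdown arrays had 900 ± 0.856 and 805 ± 35.3 (SD, n = 2).

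Of the 31605 probe sets, 4768 passed in F1, 2616 higher and 2152 lower, and 405 of the higher and 61 of the lower changed at least 2-fold. Further large rises were those of Tex13b (log2 fold change 3.48), BC080696 (2.84), the Y-linked gene Uty (2.49), D13Ertd608e (2.46), Sp110 (2.36) and Pramel18 (2.32). The largest falls were those of Hsf2bp (-1.90), Gm13261 (-1.82), Rif1 itself, Zfp229 (-1.73), the meiotic gene Hormad1 (-1.71), Srgn (-1.66), Gpt2 (-1.64), Accsl (-1.63), Tdrd12 (-1.62), Pck2 (-1.51), the histone variant gene H2ax (-1.50) and Pdcl2 (-1.49). Their adjusted p ran from 1.93e-07 for H2ax to 0.000248 for Srgn. Genes named for F1 here and below are each given at 1 probe set. None of the other tested probe sets passed in F1 for Igf2, Hand1, Sox1, Nusap1, Chaf1b and Lamc1 (0 of 1 each). The same held for Pif1 and Oip5os1 (0 of 2 each). The F1 count was 8127 with only the 4 F1 arrays, of which 4757 were among the 4768. It was 2641 and 2472 without control replicate 1 or 2, and 1856 and 2163 without Rif1 shRNA replicate 1 or 2. Of 112 named probe sets past the threshold, 107 and 105 passed without control replicate 1 or 2, and of 110 measured, 104 and 102 without Rif1 shRNA replicate 1 or 2 (adjusted p of the others from 0.0503 to 0.276). The others were those of Oip5os1, Pmepa1, Egln3, Stat3 and Ankrd37 and, for some arrays, Pif1, Mcm3ap and Slc2a3. Without the probe sets of the fibroblast, imprinted and p53 lists and of Y-linked genes the F1 count was 4654, an alternative added after the values were seen. Such an omission lowers the count mainly by the probe sets left out. It therefore cannot tell whether feeder RNA or the origin of the cells moved other genes.

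Markers of feeder fibroblasts rose with the F1 knockdown. Of 26 measured, 24 rose and 0 fell (25 and 0 adjusted over the list alone), with a median log2 fold change of 1.28 (adjusted p = 9.15e-26, and adjusted p = 0.0285 with an estimated correlation). The members Col1a1 (0.62) and Fn1 (0.12) had adjusted p of 0.0591 and 0.334. Examples were Anxa1 (1.79), Acta2 (1.66), S100a6 (1.43) and Lgals1 (1.31). On the imprinted list, 13 of 24 rose and Snrpn fell (14 and 2 adjusted over the list alone; median 0.36, adjusted p = 3.82e-07, and adjusted p = 0.115 with an estimated correlation), with Meg3 (1.72), the growth factor gene Igf2 (1.72) and Ndn (1.41) at the top. On the p53 list, 12 of 24 rose and Ei24 and Sesn2 fell (14 and 3 adjusted over the list alone; median 0.32, adjusted p = 3.06e-07, and adjusted p = 0.122 with an estimated correlation). Ddit4l (1.51), Plk2 (1.24), Phlda3 (0.92) and Ccng1 (0.76) were among the risen. The imprinted and p53 lists rose in the same arrays as the feeder fibroblast markers. Whether RNA of feeders contributed to these rises was not tested.

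**Figure D3:**
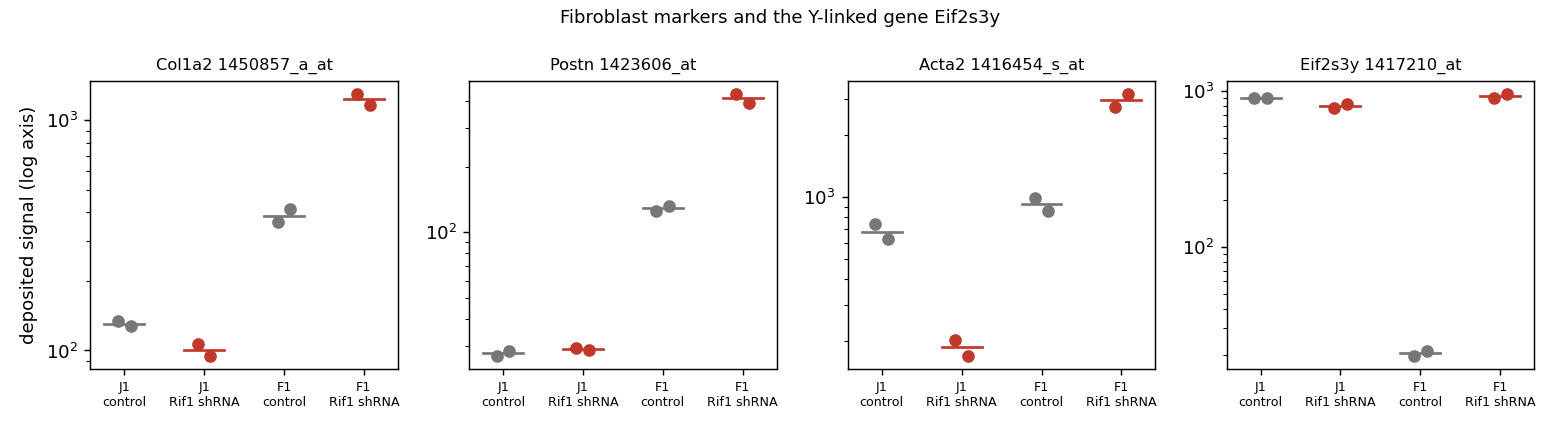
Deposited signal per array (log axis) of the fibroblast genes Col1a2, Postn and Acta2 and of the Y-linked gene Eif2s3y, in grey for control and red for Rif1 shRNA, with the mean of the 2 arrays as a line. Eif2s3y had means of 20.6 in F1 controls and 936 in F1 knockdown cells, and Acta2 fell in J1 and rose in F1.

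On the 2-cell list, 10 of 13 rose in F1 and 0 fell (11 and 1 adjusted over the list alone), with a median of 2.02 (adjusted p = 6.31e-14, and adjusted p = 0.0460 with an estimated correlation). On the trophoblast list, 7 of 17 rose (7 adjusted over the list alone; adjusted p = 0.00247, and adjusted p = 0.177 with an estimated correlation). Krt18, Krt8, Krt7 (1.58) and the homeobox gene Rhox6 (1.67) rose, while Tfap2c (-0.85) and Phlda2 fell (2 fallen adjusted over the list alone). On the streak and mesoderm list, 8 of 19 rose and 0 fell (8 and 0 adjusted over the list alone; median 0.13, adjusted p = 0.000196, and adjusted p = 0.115 with an estimated correlation). These included the transcription factor genes Cdx1 (1.70), Sp5 (1.35) and Hand1 (1.23) and the growth factor gene Bmp4 (1.08), with 5 risen without control replicate 2 and 4 without Rif1 shRNA replicate 1. On the neural list, 6 of 23 rose, with Hoxb1 (1.33) and Nr2f1 (1.05), and Sox1 (-0.95) and Pax6 (-0.67) fell (7 and 2 adjusted over the list alone; adjusted p = 0.0407, and adjusted p = 0.141 with an estimated correlation). The neural call was lost without control replicate 2 (adjusted p = 0.0600), Rif1 shRNA replicate 1 (adjusted p = 0.115) or Rif1 shRNA replicate 2 (adjusted p = 0.0686), with values as deposited (adjusted p = 0.0779) and with the filter at the 60th percentile (adjusted p = 0.119), with 3 genes risen without either Rif1 shRNA replicate.

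Genes of the cell cycle and of genome maintenance were lower in the F1 knockdown arrays, the same arrays in which feeder fibroblast markers were higher. On the DNA replication list, 19 of 47 fell and Ccne2 rose (24 and 2 adjusted over the list alone; median fell by 0.15, adjusted p = 3.74e-07, and adjusted p = 0.0460 with an estimated correlation). Mcm10 (-0.61), Pold1 (-0.58) and Pola1 (-0.53), which act at replication forks, were among them. On the mitosis list, 14 of 27 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 4.92e-07, and adjusted p = 0.115 with an estimated correlation), with Nusap1 (-0.96) and Mki67 (-0.57). On the break repair list, 14 of 35 fell and 0 rose (18 and 0 adjusted over the list alone; adjusted p = 3.75e-07, and adjusted p = 0.115 with an estimated correlation). H2ax, Dmc1 (-0.94), Mdc1 (-0.66) and Xrcc5 (-0.48) fell. Without Rif1 shRNA replicate 1 the fallen were 8 on the replication, 8 on the mitosis and 9 on the break repair list, without control replicate 2 they were 9 on the replication and 8 on the mitosis list, and without Rif1 shRNA replicate 2 they were 9 on the replication list. On the heterochromatin list, 10 of 39 fell and E2f6, Hdac2 and Rnf2 rose (15 and 3 adjusted over the list alone; adjusted p = 0.000135, and adjusted p = 0.141 with an estimated correlation). Uhrf1 (-0.54), Chaf1b (-0.56) and Morc3 (-0.46) fell, and 6 fell without Rif1 shRNA replicate 1 or replicate 2.

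On the cholesterol list, 10 of 20 fell and Hsd17b7 rose (11 and 2 adjusted over the list alone; adjusted p = 0.000135, and adjusted p = 0.189 with an estimated correlation), with Msmo1 (-0.67) and Fdft1 (-0.60), and 6 fell without control replicate 2 and 5 without Rif1 shRNA replicate 2. On the pluripotency list, 15 of 34 fell and 7 rose (18 and 9 adjusted over the list alone; median -0.24, adjusted p = 0.0338, and adjusted p = 0.154 with an estimated correlation). Esrrb (-0.54) fell and Socs3 (0.73) and Fbxo15 (0.46) rose, while Pou5f1 had 0.08 and Nanog 0.14 (adjusted p = 0.655 and 0.0898). The pluripotency call was lost without control replicate 2 (adjusted p = 0.0708) and with J1 Rif1 shRNA replicate 1 left out (adjusted p = 0.0508), with normalization within each setting (adjusted p = 0.0515) with only the F1 arrays (adjusted p = 0.0524) and with the filter at the 60th percentile (adjusted p = 0.0505). The risen were 4 without control replicate 2 or either Rif1 shRNA replicate.

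The other 7 lists did not pass in F1. On the germline list (adjusted p = 0.0887, but 0.0297 with the mean of all probe sets of a gene), 9 of 28 rose, led by Tex13b, Dazl (2.06) and Syce1 (1.87), and Hormad1, Tex14, Sycp3, Prdm1 and Smc1b fell (9 and 6 adjusted over the list alone). On the primitive endoderm list (adjusted p = 0.867), 9 of 28 rose, with Krt19 (1.38) and Sparc (0.77), and Srgn, Cubn, Lama1, Lamc1 and Apoe fell (9 and 6 adjusted over the list alone). Its median was -0.04, its mean 0.01 and its test pointed up, and 4 rose without Rif1 shRNA replicate 1. On the stress list (adjusted p = 0.835), 10 of 26 rose and 9 fell (12 and 11 adjusted over the list alone), with Nupr1 (-1.08) and the serine synthesis genes Phgdh (-0.53) and Psat1 (-0.46) among the fallen. Its median was 0.02, its mean -0.006 and its test pointed down, and 5 rose without control replicate 2, 2 without Rif1 shRNA replicate 1 and 6 without Rif1 shRNA replicate 2. On the primed epiblast list (adjusted p = 0.983), Wnt8a (1.07), Nodal (0.52), Fgf8 and Cldn6 rose and Zic5 (-0.82), Otx2 (-0.80), Enpp3, Zic2 and Dnmt3b fell among 19 (5 and 5 adjusted over the list alone). On the interferon list (adjusted p = 0.428), Gbp2 (1.20), B2m (1.10), Cxcl10 (1.04) and Ifit2 rose and Oas1a, Ifitm3 and Ifitm1 (-0.48) fell among 24 (4 and 3 adjusted over the list alone). On the glycolysis and hypoxia list (adjusted p = 0.835), Adm, P4ha2, Ankrd37 and Slc2a3 rose and Egln3 (-0.90) and Pdk1 fell among 27 (6 and 6 adjusted over the list alone). On the telomere list (adjusted p = 0.473), Pif1 (-0.53), Dkc1 (-0.34), Terf1 and Ruvbl2 fell among 28 and 0 rose (4 and 0 adjusted over the list alone). The medians of the telomere and primed epiblast lists, -0.03 and -0.05, were 0.005 and 0.005 with values as deposited.

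**Figure D4:**
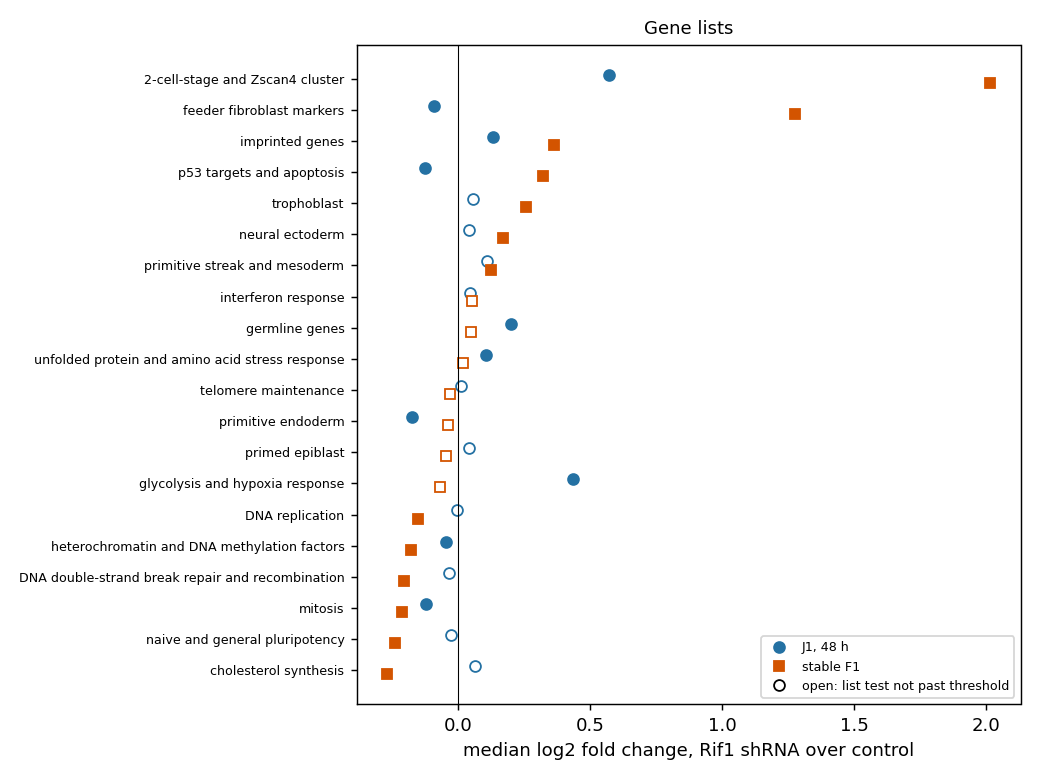
Median log2 fold change of Rif1 shRNA over control (horizontal axis) for the 20 gene lists, as circles for J1 and squares for F1, filled where the list test with a preset correlation passed. The fibroblast list stood at -0.09 in J1 and 1.28 in F1, and the glycolysis list at 0.44 and -0.07.

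The effects in the 2 settings were then compared. Keratins and fibroblast markers were among the genes that differed: Krt18 by 3.75 and Krt8 by 3.56 on the log2 scale (F1 minus J1), Acta2 by 3.54 and Tagln by 2.56, since both of the latter fell in J1 and rose in F1. Eif2s3y (4.26) and Tex13b (3.49) were higher in the F1 effect as well. Tex13b passed the filter on dim probe sets only through the 2 F1 Rif1 shRNA arrays. Its J1 effect was thus measured on dim signals and does not show a lack of response in J1. On the other side stood Gm13261 (-2.12), Hsf2bp (-2.03), the hypoxia genes Bnip3 (-1.97) and Egln3 (-1.93), Gpt2 (-1.88) and Pdcl2 (-1.80). Adjusted p of these 12 genes ran from 1.16e-08 for Eif2s3y to 0.0111 for Bnip3, which did not pass without J1 control replicate 1 (adjusted p = 0.0560) or F1 control replicate 2 (adjusted p = 0.0557). In all, 2644 of 31605 probe sets differed, 1578 with a higher and 1066 with a lower effect in F1. The fibroblast list differed by a median of 1.27 (22 of 26 higher, 24 adjusted over the list alone; adjusted p = 2.64e-28, and adjusted p = 0.0237 with an estimated correlation). Cell line, strain, duration and delivery differed together between the settings, so the comparison cannot separate them. The count was 3995 without J1 Rif1 shRNA replicate 1, 1439 and 1383 without F1 control replicate 1 or 2, and 1014 and 1117 without F1 Rif1 shRNA replicate 1 or 2.

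The last comparison asked which genes changed in both settings. AF067061, Gm20767, Usp17la, H1f2, Tcstv3 and Slc25a31 rose in both, and Rif1, AU018091, Lamc1, Cbr3, Mcm3ap and Tfap2c fell in both. With 1 probe set per gene, 128 of 14714 genes were higher in both, against 29.1 for independent lists (two-sided Fisher exact test, adjusted p = 1.29e-52 over 4 tests). Lower in both were 66, against 26.2 (adjusted p = 5.05e-12). Lower in J1 and higher in F1 were 60, against 34.1 (adjusted p = 1.73e-05), and higher in J1 and lower in F1 were 25, against 22.4 (adjusted p = 0.577). Both comparisons came from one fit with one spread per probe set. A gene with a small spread thus passes more easily in both, in any direction. The counts for independent lists leave this out, so these Fisher p-values may be too small. Across genes, which are not independent replicates, the fold changes correlated with r = 0.14 and rho = 0.08. The 194 genes that moved the same way were 81 and 66 without J1 control replicate 1 or 2, 95 and 93 without F1 control replicate 1 or 2, and 75 and 83 without F1 Rif1 shRNA replicate 1 or 2.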

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

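All tests of explanations in this part were chosen after the results were seen, and so were the bounds that decided the feeder, Y chromosome and single-culture tests; the tests of the difference between settings were not.

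The effect of Rif1 shRNA differed between F1 and J1 for 2644 probe sets, by the interaction term of the limma fit. By the same term, 94 of 117 named genes differed, 53 with a higher and 41 with a lower effect in F1. The named genes were picked for their changes in these same fits, so this share does not describe genes at large. Of all tested probe sets, 8.37% differed. The difference of log2 fold changes, F1 minus J1, was Eif2s3y 4.26, Krt18 3.75, Krt8 3.56, Acta2 3.54, Tex13b 3.49, Tagln 2.56, Col5a2 2.54, Uty 2.53, Anxa1 2.41, Vgll3 2.29, Prss23 2.25, Tcstv1 2.17, Lpp 1.90 and Meg3 1.84. Next came S100a6 1.84, Syce1 1.77, Hoxb1 1.68, Cdx1 1.66, Krt7 1.61, Igf2 1.57, Cxcl10 1.503, D13Ertd608e 1.45, Pramel18 1.45, Gbp2 1.34, Pmepa1 1.32, Rhox6 1.31, Sp5 1.24 and Rc3h2 1.20. These were followed by Phlda3 1.20, Lgals1 1.19, Ccng1 1.18, Krt19 1.18, Wnt8a 1.16, Sp110 1.14, Ddit4l 1.12, Nr2f1 1.11, Hand1 1.11, BC080696 1.09, Sfmbt1 1.08, Ndn 1.06, Plk2 1.06 and Prkca 1.02. Smaller differences were Socs3 0.96, Sparc 0.94, B2m 0.91, Stat3 0.91, Dazl 0.74, Mest 0.72, Bmp4 0.72, Nodal 0.65, Tcstv3 0.62, Usp17la 0.56 and Fbxo15 0.26. In the other direction the difference was Dkc1 -0.33, Bub1b -0.33, Ccnb2 -0.38, Pola1 -0.40, Pgk1 -0.46, Xrcc5 -0.48, Mcm10 -0.49, Esrrb -0.50, Uhrf1 -0.52, Fdft1 -0.55, Morc3 -0.56, Psat1 -0.56, Phgdh -0.57 and Fdps -0.58. Larger negative differences were Mdc1 -0.60, Ifitm1 -0.65, Gm20767 -0.66, Rif1 -0.66, Chaf1b -0.72, Cth -0.73, Msmo1 -0.76, Nusap1 -0.81, Otx2 -0.85, Zic5 -0.91, Aldoc -0.99, Sox1 -1.20, Dmc1 -1.21 and H2ax -1.26. The most negative were Nupr1 -1.43, Abcf2 -1.44, Tdrd12 -1.45, Zfp229 -1.53, Accsl -1.61, Pck2 -1.63, Hormad1 -1.71, Pdcl2 -1.80, Gpt2 -1.88, Egln3 -1.93, Bnip3 -1.97, Hsf2bp -2.03 and Gm13261 -2.12.

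By camera on the same term, 12 lists differed, and only the fibroblast list did so with an estimated correlation. The median difference (F1 minus J1) was 1.27 for the fibroblast list (adjusted p = 2.64e-28, and adjusted p = 0.0237 with an estimated correlation) and 0.65 for the 2-cell list (adjusted p = 1.11e-07, and adjusted p = 0.135 with an estimated correlation). It was 0.46 for the p53 list (adjusted p = 2.62e-10, and adjusted p = 0.135 with an estimated correlation) and 0.24 for the imprinted list (adjusted p = 0.000178, and adjusted p = 0.256 with an estimated correlation). Next it was 0.16 for the primitive endoderm list (adjusted p = 0.0379, and adjusted p = 0.369 with an estimated correlation) and 0.0770 for the streak and mesoderm list (adjusted p = 0.0131, and adjusted p = 0.256 with an estimated correlation). Lower medians were 0.0752 for the trophoblast list (adjusted p = 0.0343, and adjusted p = 0.369 with an estimated correlation) and -0.11 for the mitosis list (adjusted p = 0.0343, and adjusted p = 0.371 with an estimated correlation). Further down it was -0.16 for the DNA replication list (adjusted p = 7.27e-06, and adjusted p = 0.0758 with an estimated correlation) and -0.20 for the break repair list (adjusted p = 5.28e-05, and adjusted p = 0.256 with an estimated correlation). The lowest were -0.31 for the cholesterol list (adjusted p = 0.000309, and adjusted p = 0.301 with an estimated correlation) and -0.41 for the glycolysis and hypoxia list (adjusted p = 8.55e-07, and adjusted p = 0.369 with an estimated correlation). The 0.65 of the 2-cell list covers 13 of its 51 names and leaves out probe sets that match several loci. Some of those tested went the other way, with differences of -1.34, -1.50, -0.89 and -0.70 (limma adjusted p = 6.92e-05, 0.000413, 0.00102 and 0.0222). The others had 1.68, 1.34 and 0.39 (limma adjusted p = 0.000249, 0.000468 and 0.185).

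Fibroblast markers rose in F1 knockdown cells and not in J1 cells. Scaling of the arrays is argued against, since the lowest list median over 3 scalings was 1.28. The trimmed means of the F1 arrays differed by a ratio of only 1.03, so the scalings had little room to lower it. More feeder RNA in the knockdown cultures would raise the feeder genes by one ratio. The 14 members with a J1 control signal under 150 had an SD of log2 fold changes of 0.350. This SD lay at percentile 50.23 of 10000 random sets of genes risen in F1, within simulation error of the bound of 50. The test cannot decide this, since the random sets held only genes already called higher. The J1 cultures also had feeders, so a low J1 signal may leave out genes that feeders express strongly. The levels differ in what stem cells add as well, so more feeder RNA cannot be told apart from a change within the F1 cells. The stable knockdown itself stays open as an untested biological explanation.

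The Y-linked genes Eif2s3y and Uty were near background in F1 controls only, with the brightest Uty probe set at 6.12 ± 2.02 there and 143 ± 1.32 in F1 knockdown cells (SD, n = 2). A larger share of male feeder RNA is argued against. The rise of Eif2s3y exceeded the highest of the fibroblast list by 2.33 on the log2 scale. The Eif2s3y control signal is near background, and the offset shrinks both changes. With log2 ratios of deposited signals the gap was 3.51, against Col5a2. Feeders of different sex in the control and knockdown cultures were not tested. An exchange of the F1 labels is argued against, since Rif1 was lower at 4 of its 4 probe sets in the arrays labelled Rif1 shRNA. Loss of the Y chromosome in the F1 control line may account for it. Only 2 Y-linked genes were above the 40th percentile on all J1 arrays, both below it in F1 controls. That is too few to decide, since the test asked for at least 4 such genes to favour the loss. Usp9y fell in F1, from 89.8 ± 14.4 to 36.7 ± 9.89 (SD, n = 2). Its J1 signal was 46.4 ± 6.00 in controls and 54.0 ± 4.53 in knockdown arrays (SD, n = 2), near the 40th percentile. This probe set therefore cannot speak for or against the loss. F1 control and knockdown cells may thus differ in origin as well as in Rif1, which bears on every F1 result.

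Glycolysis and hypoxia genes were higher as a list in J1 Rif1 shRNA cultures. Scaling is argued against, since the lowest list median over 3 scalings was 0.42. The trimmed means of the J1 arrays differed by a ratio of only 1.02, so here too the scalings had little room to lower it. Without Rif1 shRNA replicate 2 the median was 0.24 and the list test with a preset correlation still passed; the SD between the medians with either knockdown array alone was 0.266, a bound that grows with the effect of replicate 2 itself and so leans towards leaving this open. The genes of this list moved together (estimated correlation 0.596) and the call with all arrays was lost with an estimated correlation (adjusted p = 0.244), so an effect of the knockdown cannot be told apart from the state of one culture. No biological explanation was tested.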

How the results depend on the processing

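Added after the values were seen were the tests with values as deposited, normalization within each setting, the crossed block and the omission of 3 lists and Y-linked genes. Among the lists in J1 and F1 and the named genes, no result past the threshold changed direction in the alternatives run. For the difference, its count, its 12 named genes and the Rif1 probe sets were run again. Its lists were run again only with an estimated correlation and by the fry test described below. The planned quantile normalization was the setting used throughout. The J1 count of 1004 was 350 with no intensity trend, 280 with its own 4 arrays, 1911 at an adjusted p under 0.1, and 45 at an unadjusted p under 0.05 and 2-fold. It held more higher than lower probe sets with no intensity trend, with its own 4 arrays (152 and 128), without either replicate 2 and at 2-fold (36 and 9), the reverse of 455 and 549. The F1 count of 4768 was 8127 with its own 4 arrays and 466 at an unadjusted p under 0.05 and 2-fold. The count for the difference, 2644, was 4058 at an adjusted p under 0.1 and 478 at an unadjusted p under 0.05 and 2-fold. The overlap of 194 was 73 with no intensity trend. With an estimated correlation 0 of 10 lists passed in J1 and 3 of 13 in F1. The fry test asks whether the genes of a list move one way on balance, without comparing them with other genes, so it is another question than that of camera. By fry the p53, heterochromatin, imprinted and glycolysis lists did not pass in J1 (adjusted p = 0.0643, 0.0947, 0.0543 and 0.0543), while the pluripotency list passed in J1 (0.0433) and the germline list in F1 (0.00202). The 13 lists that passed by camera in F1 all passed by fry. For the difference, the mitosis and glycolysis lists did not pass by fry (adjusted p = 0.0759 and 0.109). The other lists that differed by camera did. The neural and stress lists passed by fry alone (adjusted p = 0.0245 and 0.0123). With the replicate number as a block the counts were 468 in J1, 3684 in F1, 1709 for the difference and 91 for the overlap; same-numbered arrays correlated at -0.34 in J1 and 0.19 in F1, which does not settle whether arrays of a number were handled together. With crossed pairs the counts were 1088, 5196 and 3001. With values as deposited 896 passed in J1 and 6209 in F1, and with normalization within each setting 905 and 6317. With 1 array left out, where the lone array is assumed to vary like the other groups, the ranges were 229 to 1763 in J1, 1856 to 6211 in F1, 1014 to 3995 for the difference, 66 to 251 for the overlap, 8 to 11 lists in J1 and 11 to 13 in F1. Rif1 ranged from -1.21 to -0.93 in J1 and from -1.79 to -1.72 in F1. Of 53 named J1 probe sets, 37 stayed past the threshold without control replicate 1 and 35 without control replicate 2; of 112 in F1, all did with the 4 F1 arrays only, and with no intensity trend 108 did, against 38 of 53 in J1. The causes were not tested. Probe sets near background, such as those of Kdm5d, were left out by the filter and have no fold change.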

Other observations

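The tests of distal genes by list were chosen before their results were seen, and the count of distal calls and the probe sets below were chosen after.

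Several probe sets of 2-cell-stage genes match more than 1 locus and so name no gene. The probe set with 4 of its 6 loci on the 2-cell list rose 14.3-fold in J1, from 124 ± 6.24 to 1818 ± 139, and 5.62-fold in F1, from 1544 ± 169 to 7641 ± 267 (SD, n = 2; limma adjusted p = 1.74e-09 and 2.09e-08). A tested probe set with 3 of 3 loci on the list rose 12.3-fold in J1 and 4.36-fold in F1. Of the 5 other tested probe sets of this kind, each with 1 locus on the list, 2 rose 11.2-fold and 10.6-fold in J1 and 6.02-fold and 6.57-fold in F1. Another rose more in F1, 1.72-fold in J1 and 5.54-fold in F1, and 1 rose only in F1, 3.05-fold against 1.21-fold in J1 (limma adjusted p = 0.238). The last passed in neither setting (limma adjusted p = 0.956 and 0.0530). The long noncoding RNA Xist, at its brightest probe set, rose in F1 from 112 ± 7.91 to 198 ± 9.51 (SD, n = 2; limma adjusted p = 0.00600).

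As Rif1 acts at telomeres, its knockdown might raise genes near chromosome ends. Over 423 measured genes among the 30 outermost of the distal end of each of 20 chromosomes, camera of limma gave an unadjusted value of 0.578 in J1 and 0.394 in F1 (adjusted p = 0.578 for both), with medians of 0.01 and -0.008 against 0.006 and -0.02 for other genes. A shift of these genes as a set was not detected. By calls, 15 of the 423 rose in J1, 3.55% against 1.81% of other genes (two-sided Fisher exact test, p = 0.0157, adjusted p = 0.0314 over 2 tests). In F1, 55 rose, 13% against 10.6% (two-sided Fisher exact test, p = 0.110, adjusted p = 0.110). Neighbouring genes are not independent, so these p-values may be too small, and a few strongly changed neighbours could give such an excess.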
